A study of Mus musculus with 28 samples.

How the data were processed

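RNA was sequenced from whole mouse skin in 28 libraries, each from a different mouse as far as the labels state. The mice were 12-week-old females whose hair was removed 5 days earlier. Ultraviolet B light (UVB) was given at 500 mJ/cm² to the UV groups, and the NoUV groups received none. Titles and design text place the harvest 3 h after UV, whereas the treatment protocol states 1 day. The values carry both readings, and the conflict was not settled by the labels. The labels name skin, while the title of the series names epidermis.

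The libraries were prepared from ribosome-depleted total RNA and read in pairs. Per the labels, reads were trimmed with cutadapt 4.6, aligned with HISAT2 2.1.0 and counted per gene with featureCounts of the Subread package, whose version is not given. The deposited values of each experiment are raw counts per gene, without normalization by the authors. Settings for strand and for reads with several alignments are not stated. Near-identical genes therefore have uncertain counts, among them the late cornified envelope genes (Lce1 family) and the histone genes.

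The whole-body experiment holds 55573 genes. Of its 55394 genes with a matching identifier in the GENCODE M21 annotation of GRCm38, 99.68% had the listed position. The keratinocyte experiment holds 57126 genes, and 2.76% of 51884 matching genes had the GRCm38 position, although the notes name that build for all libraries. Genes were joined between experiments by identifier, never by position. No column was left unused.

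Total counts per library ran from 30.47 to 43.84 M in the whole-body experiment and from 7.12 to 31.14 M in the keratinocyte experiment. At these depths, 3 counts set the floor below which a group mean was not read. This floor covers counting error only, since no molecular identifiers were used, whereas the 95% intervals of log2 differences come from the SE of the fit and include variation between mice. Xist counts of at least 19159 per library and at most 6 counts from Y-linked genes matched the stated sex. Replicates were checked against each other for duplicated libraries, and none was found.

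Groups were taken from the titles. The whole-body experiment compares wild-type mice (WT) with mice lacking Vsir in all cells (KO), 3 libraries per group. The keratinocyte experiment compares mice with floxed Vsir and no Cre recombinase (FL) with floxed mice carrying K14Cre, which is active in keratinocytes (cKO), 4 libraries per group. The experiments carry different batch dates, so they were fitted separately. Comparisons across them were made only between differences taken within each, in 1 joint model of the 8 groups.

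Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, its filter on expression, robust quasi-likelihood fits and 1 coefficient per group. P values are two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Genes tested numbered 20365 in the whole-body experiment, 19718 in the keratinocyte experiment and 21851 in the joint model. Levels are given as counts per M (CPM) after TMM scaling, as mean ± SD. Changes are log2 fold changes (log2FC) with the standard error (SE) of the fit, and 3 was the prior count of log2 values. A gene that is called passed the adjusted threshold.

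The following choices were fixed before the data were examined. Genes were named by a rule: Vsir; the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 2 and no overlap between groups, omitting predicted, mitochondrial and hair keratin-associated genes; 14 fixed genes of interferon, inflammation, DNA damage, epidermal stress and PD-L1; up to 4 members per list with the smallest p; and called genes within 5 Mb of Vsir in genotype comparisons. Any gene named outside the rule is marked as chosen after its values were seen.

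Gene lists numbered 29. The 14 pathway lists were interferon-stimulated genes, interferon ligands and sensors, interferon gamma and antigen presentation, inflammatory cytokines, p53 targets, immediate early genes, NRF2 targets, heat shock, keratinocyte stress, epidermal differentiation, basal keratinocyte, cell cycle, circadian clock, and checkpoints with VISTA partners. The 15 cell type lists were growing (anagen) hair follicle, sebaceous gland, melanocyte, fibroblast, endothelial, macrophage, dendritic and Langerhans, T cell, B and plasma cell, neutrophil, mast cell, skeletal muscle, adipocyte, Schwann and erythroid. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 29 lists of a comparison, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. Each list also received a score per library, the mean log2 CPM of its members, which was compared between groups by exact permutation within strata. In 35 of 290 list tests, the median, mean and test differed in sign, and 0 of these passed the threshold.

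Alternatives planned were RLE size factors, no expression filter, DESeq2 1.42.0, only the groups of the comparison, a block for replicate number, covariates for skeletal muscle and anagen scores, a block for the number series of the original sample names, each library left out, and a stricter adjusted p of 0.01 for shared calls. Replicate numbers come from the titles, which do not say whether equal numbers mark shared litters or days. Deviations from the group mean were correlated across genes between libraries of equal number. They correlated positively in every pair only for UV in KO (r 0.128 to 0.176) and UV in cKO (r 0.229 to 0.486). The blocked values are in the closing section, and for UV in KO and UV in cKO also beside a result whose call they changed. Added after the values were seen were fits without FL_NoUV 1 and cKO_UV 3 (the shallow libraries), without WT_NoUV 3 and WT_UV 3 (high anagen score), without KO_NoUV 2 and KO_UV 3 (low Gm42418, an RNA over ribosomal DNA), a covariate for body position from Hoxa9, Hoxa10, Hoxb9 and Hoxc10, and the genotype effect averaged over treatments.

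Recovery was tested on simulated data with 200 changed genes per comparison. Genes were drawn independently, without variation shared between genes, and the real UV comparisons called more genes (3817 for UV in WT). The rates therefore hold for the simulated setting and may differ in the real data. For UV in WT, 28.4% of 2-fold and 83.3% of 4-fold changes were called. The values were 31.3% and 81.8% for KO against WT, 31.3% and 77.3% for UV in FL, 29.9% and 68.2% for cKO against FL, and 9% and 33.3% for genotype effects compared between experiments. Figures and exact tests used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.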

Results

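Skin transcripts were counted in 28 libraries from 2 experiments on VISTA, an inhibitory immune checkpoint protein encoded by Vsir. The whole-body experiment had 3 libraries per group: wild-type (WT) and Vsir knockout (KO) mice, each without UV (NoUV) and after 500 mJ/cm² UVB (UV). The keratinocyte experiment had 4 libraries per group: floxed controls (FL) and mice with K14Cre directed to keratinocytes (cKO), each without and after UV. Titles give 3 h from UV to harvest, and the treatment protocol gives 1 day. Total counts in the whole-body experiment were 43.84, 32.74 and 33.87 M in WT_NoUV, 31.66, 37.38 and 35.19 M in WT_UV, 36.8, 38.34 and 34.36 M in KO_NoUV, and 30.57, 30.47 and 38.21 M in KO_UV. In the keratinocyte experiment they were 7.12, 22.28, 29.75 and 30.51 M in FL_NoUV, 22.05, 26, 31.14 and 23.77 M in cKO_NoUV, 22.29, 15.48, 26.02 and 23.24 M in FL_UV, and 24.11, 26.39, 7.51 and 21.5 M in cKO_UV. The first principal component held 62.5% of the variance in the whole-body experiment and separated UV from NoUV libraries. In the keratinocyte experiment it held 46.9% and followed hair follicle genes, while UV separated along the second, with 17%.

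Vsir (ENSMUSG00000020101, chromosome 10, GRCm38 60346851 to 60372684) was lower in every KO library than in every WT library. Without UV its mean was 6.14 ± 0.95 CPM in KO and 38.39 ± 6.65 CPM in WT (n = 3 each, log2FC −2.64, SE 0.23, adjusted p = 0.00047). After UV it was 2.99 ± 0.92 CPM in KO and 22.05 ± 1.88 CPM in WT (log2FC −2.89, SE 0.24, adjusted p = 0.000332). Vsir fell after UV in WT (log2FC −0.80, SE 0.22, adjusted p = 0.0223) and in KO (log2FC −1.05, SE 0.23, adjusted p = 0.00642). The fall in WT missed the threshold without WT_NoUV 1 (adjusted p = 0.0521), WT_UV 1 (adjusted p = 0.0502) or WT_UV 2 (adjusted p = 0.0599), with only the 2 groups compared (adjusted p = 0.0527), or without WT_NoUV 3 and WT_UV 3 together (adjusted p = 0.0601). The fall in KO missed it with tissue covariates (adjusted p = 0.0722) or without KO_NoUV 2 and KO_UV 3 together (adjusted p = 0.0837). UV against NoUV was called for Vsir in 0 of 25 fits in FL (log2FC 0.06 to 0.5) and 0 of 25 in cKO (log2FC −0.55 to 0.2). Its UV effect in WT minus that in FL was not called by edgeR in the joint model (log2 difference −0.997, adjusted p = 0.278). In the keratinocyte experiment Vsir was not called. Its mean was 33.84 ± 11.95 CPM in cKO and 25.31 ± 8.91 CPM in FL without UV (n = 4 each, log2FC +0.41, SE 0.32, adjusted p = 0.923), and 28.04 ± 10.88 CPM against 29.54 ± 4.83 CPM after UV (log2FC −0.07, SE 0.32, adjusted p = 0.986). Counts per gene do not separate the floxed exons from the rest of the transcript, and whole skin holds cells without K14Cre.

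**Figure D1:**
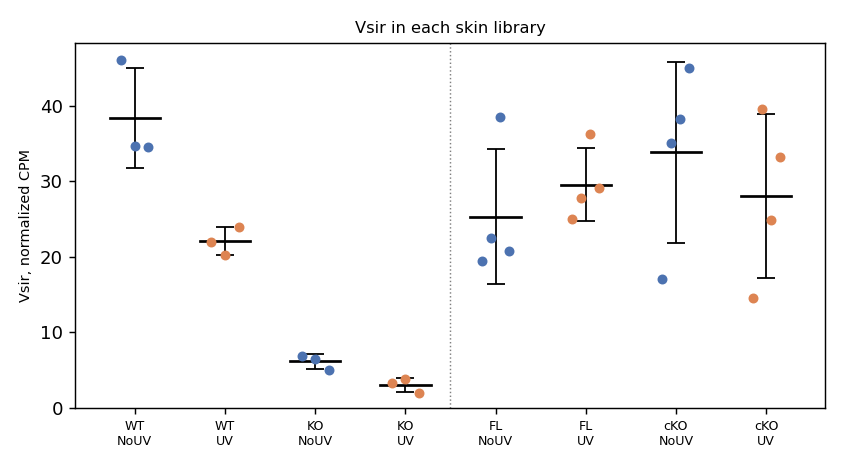
Vsir level in each library as normalized counts per M (vertical axis) by group (horizontal axis). Points are libraries, bars mean ± SD, and the dotted line parts the whole-body experiment from the keratinocyte experiment; the highest KO library stands at 6.87 and the lowest WT library at 20.21.

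UV in WT skin asked which genes respond to acute UVB with VISTA present. Chemokines that attract monocytes and neutrophils rose: Ccl7 reached 55.45 ± 16.83 CPM after UV against 6.31 ± 3.45 CPM without (n = 3 each, log2FC +3.13, SE 0.42, adjusted p = 0.000572). Cxcl1 reached 14.56 ± 2.46 CPM against 1.36 ± 0.51 CPM (log2FC +3.40, SE 0.66, adjusted p = 0.00386). Cdkn1a, which encodes the p53-induced cell cycle inhibitor p21, reached 346.61 ± 100.03 CPM against 166.27 ± 47.61 CPM (log2FC +1.06, SE 0.26, adjusted p = 0.0135). Lce1d, a component of the cornified envelope, fell from 61.78 ± 14.4 CPM to 6.33 ± 1.02 CPM (log2FC −3.29, SE 0.35, adjusted p = 0.000199). Interferon-stimulated genes were not called: Ifit1 had a log2FC of +0.82 (adjusted p = 0.441), Isg15 of +0.44 (adjusted p = 0.666), Mx1 of +0.74 (adjusted p = 0.268) and Irf7 of +0.46 (adjusted p = 0.518).

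The test called 3817 of 20365 genes in WT, 1814 higher and 2003 lower, and the count was 1288 with only the 2 groups compared, 2542 with tissue covariates and 2157 without WT_NoUV 3 and WT_UV 3 together. The stress-induced factor Atf3 rose from 11.83 ± 1.42 to 43.35 ± 17.77 CPM, and the pattern recognition gene Ptx3 from 1.64 ± 0.18 to 14.09 ± 7.57 CPM. Among other rises were Ccl2 (log2FC +2.38), Ier3 (+2.30), Jun (+1.54), the growth arrest gene Gadd45a (+1.22) and the metal-binding genes Mt2 (+1.88) and Mt1 (+1.69). Among rises of muscle and fuel-use genes, Trim63 had a log2FC of +2.62, Pdk4 of +2.59 and the fast myosin gene Myh1 of +2.52, while the fast myosin gene Myh4 fell (−0.98). The Lce1 members Lce1g (−4.14), Lce1e (−3.36), Lce1i (−3.27) and Lce1l (−2.81) fell, although reads shared between such near-identical genes leave the single values uncertain. Il1a (−1.80), the T cell gene Trac (−1.91) and the dendritic cell migration receptor Ccr7 (−3.29) also fell. The rise of Cdkn1a missed the threshold without WT_UV 2 (adjusted p = 0.0588) or WT_NoUV 3 (adjusted p = 0.0517).

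Of the 29 lists, 3 passed in WT, all lower after UV. Cell cycle had 5 of 20 members lower over all genes and 7 adjusted over the list alone (adjusted p = 0.00323, and adjusted p = 0.973 with an estimated correlation). Epidermal differentiation had 5 of 25 lower on either basis (adjusted p = 0.00707, and adjusted p = 0.973 with an estimated correlation), and missed the threshold without WT_UV 1 (adjusted p = 0.0973). T cell genes had 2 of 13 lower and 3 adjusted over the list alone (adjusted p = 0.0148, and adjusted p = 0.973 with an estimated correlation), and missed the threshold without WT_NoUV 3 (adjusted p = 0.059). The inflammatory list did not pass (adjusted p = 0.153), with 6 members higher and 3 lower over all genes, and 9 and 3 adjusted over the list alone. Of the p53 list, 7 members rose and 2 fell over all genes, and 9 and 3 adjusted over the list alone (adjusted p = 0.193). Interferon-stimulated genes had 0 of 40 members called by edgeR on either basis (adjusted p = 0.886). Hoxc10, a gene of posterior body position, had at most 2 counts in any NoUV library and at least 137 in any UV library of this experiment. It was chosen after its values were seen, as was Hoxb9 (log2FC +2.81 in WT and +3.06 in KO), so UV and NoUV samples differed in a marker of body position.

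UV in KO skin asked for the same response without VISTA. Ccl7 reached 130.56 ± 32.89 CPM against 9.94 ± 3.03 CPM (n = 3 each, log2FC +3.71, SE 0.43, adjusted p = 0.000169). The cytokine gene Il6 reached 6.74 ± 1.06 CPM against 0.83 ± 0.96 CPM (log2FC +3.03, SE 0.65, adjusted p = 0.00552). The antiviral gene Oas2 rose from 8.01 ± 1.53 to 33.29 ± 13.34 CPM (log2FC +2.05, SE 0.38, adjusted p = 0.00236). Trac, which encodes the constant part of the T cell receptor alpha chain, fell from 5.86 ± 0.9 to 1 ± 0.4 CPM (log2FC −2.56, SE 0.36, adjusted p = 0.000532). Cdkn1a rose from 136.67 ± 29.37 to 261.53 ± 57.65 CPM (log2FC +0.94, SE 0.26, adjusted p = 0.0203).

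In KO, 4552 genes were called, 2300 higher and 2252 lower, and the count was 2832 without KO_NoUV 2, 2992 without KO_UV 3 and 1468 without both. It was 2691 with tissue covariates and 7493 with only the 2 groups compared. The interferon-induced genes Mx1 (log2FC +1.48, adjusted p = 0.0253) and Irf7 (+1.40, adjusted p = 0.0362) rose. Both missed the threshold without KO_NoUV 1 (0.0904 and 0.115), KO_NoUV 2 (0.0928 and 0.0736), KO_NoUV 3 (0.0589 and 0.115), KO_UV 2 (0.103 and 0.132) or KO_UV 3 (0.0503 and 0.0687). Irf7 also missed it without KO_UV 1 (0.0581) and with a replicate block (0.0556). Cdkn1a missed it without KO_UV 1 (0.106), KO_NoUV 2 (0.0623) or KO_NoUV 3 (0.1). Ifit1 (+1.09, adjusted p = 0.266), Isg15 (+0.84, adjusted p = 0.347) and Cxcl10 (−1.86, adjusted p = 0.069) were not called, and Cxcl10 was called with the block (adjusted p = 0.0295). Ptx3 (+3.91), Slfn4 (+3.22), Cxcl1 (+2.69), Ccl2 (+2.57) and the neutrophil alarmin S100a8 (+2.44) rose. The hair follicle genes Sox21 (−3.14), Lgr5 (−2.79) and Hoxc13 (−2.50) fell, as did Lce1d (−3.34) and the cross-presenting dendritic cell receptor Xcr1 (−2.64).

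In KO, 6 lists passed. T cell genes fell in 7 of 13 members over all genes and in 9 adjusted over the list alone (adjusted p = 0.000137, and adjusted p = 0.399 with an estimated correlation). Dendritic and Langerhans genes fell in 4 of 10, and adjusted over the list alone 1 rose and 6 fell (adjusted p = 0.00802, and adjusted p = 0.399 with an estimated correlation). Cell cycle fell in 3 of 20 on either basis (adjusted p = 0.00239), and epidermal differentiation in 5 of 25 and in 3 adjusted over the list alone (adjusted p = 0.00824), both with adjusted p = 0.86 with an estimated correlation. Neutrophil genes rose in 4 of 9 and in 5 adjusted over the list alone (adjusted p = 0.0469, and adjusted p = 0.86 with an estimated correlation). Interferon-stimulated genes rose in 6 of 40 and in 4 adjusted over the list alone (adjusted p = 0.0475, and adjusted p = 0.86 with an estimated correlation). With a replicate block, the neutrophil and interferon lists each had adjusted p = 0.0628. The T cell and dendritic lists were called whichever library was left out. Without KO_UV 2 the cell cycle (0.0624), epidermal (0.1), neutrophil (0.0905) and interferon lists (0.457) all missed the threshold. The interferon list also missed it without KO_NoUV 1 (0.193), KO_NoUV 3 (0.0727) or WT_NoUV 3 (0.0541), the neutrophil list without KO_NoUV 1 (0.11), KO_NoUV 2 (0.0617), KO_UV 3 (0.0558) or WT_NoUV 3 (0.0541), and the epidermal list without KO_NoUV 3 (0.056). Inflammatory genes had 8 members higher and 3 lower over all genes, 10 and 3 adjusted over the list alone, and the list did not pass (adjusted p = 0.123).

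The difference of the UV effect between KO and WT asked whether loss of VISTA altered the response. For Irf7 the UV effect was higher in KO by a log2 difference of +0.94 (95% interval −0.26 to 2.14, n = 3 per group, adjusted p = 0.9999), which was within error. The Il6 difference was +1.24 (95% interval −0.50 to 2.97) and that of Cxcl1 −0.71 (95% interval −2.39 to 0.97). For Cdkn1a it was −0.12 and for Vsir −0.25. By edgeR, 0 genes were called, 313 had an unadjusted p under 0.05, and DESeq2 also called 0. Among the lists, 7 passed. Interferon-stimulated genes had a median difference of +0.48, above 0 in 36 of 40 members (adjusted p = 7.2e-05, and adjusted p = 0.904 with an estimated correlation). The interferon list missed the threshold without WT_NoUV 1 (adjusted p = 0.191), WT_UV 2 (adjusted p = 0.0564) or KO_UV 2 (adjusted p = 0.323). T cell genes had a median difference of −0.39 (adjusted p = 7.2e-05) and dendritic genes of −0.34 (adjusted p = 0.00578), both with adjusted p = 0.394 with an estimated correlation. Skeletal muscle had a median difference of −0.42 (adjusted p = 3.8e-08, and adjusted p = 0.711 with an estimated correlation). Interferon ligands and sensors and macrophage genes (adjusted p = 0.039 each) and fibroblast genes (adjusted p = 0.0473) had adjusted p = 0.711, 0.904 and 0.904 with an estimated correlation. Over all genes 0 members of these lists were called by edgeR, and adjusted over the list alone 1 muscle gene was lower. Without WT_NoUV 1, muscle alone of the 7 passed: T cell had adjusted p = 0.119, dendritic 0.134, fibroblast 0.276, ligands and sensors 0.295 and macrophage 0.615. Dendritic genes also missed it without KO_NoUV 2 (0.0627) or WT_UV 1 (0.164), and macrophage genes without KO_NoUV 1 (0.292), KO_NoUV 2 (0.0693), KO_UV 2 (0.536), WT_NoUV 3 (0.259) or WT_UV 1 (0.666). Ligands and sensors missed it without KO_NoUV 1 (0.17), KO_NoUV 2 (0.101), KO_UV 2 (0.254), KO_UV 3 (0.0573), WT_NoUV 3 (0.119) or WT_UV 1 (0.228). Fibroblast genes missed it without KO_NoUV 1 (0.217), KO_NoUV 2 (0.154), KO_UV 1 (0.116), KO_UV 2 (0.270), WT_NoUV 3 (0.556), WT_UV 1 (0.0609) or WT_UV 2 (0.319).

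UV in FL skin asked for the response of the controls of the keratinocyte experiment. Atf3 rose from 2.87 ± 1.03 to 25.15 ± 4.32 CPM (n = 4 each, log2FC +3.10, SE 0.28, adjusted p = 3.1e-05). Il6 rose from 0.63 ± 0.41 to 5 ± 1.08 CPM (log2FC +3.11, SE 0.54, adjusted p = 0.00236), and Cxcl1 from 0.48 ± 0.18 to 7.04 ± 4.06 CPM (log2FC +3.85, SE 0.52, adjusted p = 0.000568). Pmaip1, a p53-induced gene of cell death, rose from 10.75 ± 3.07 to 50.69 ± 17.57 CPM (log2FC +2.25, SE 0.30, adjusted p = 0.000651). The interferon-induced gene Ifit1 rose from 4.96 ± 1.08 to 12.42 ± 3.8 CPM (log2FC +1.33, SE 0.25, adjusted p = 0.0041), and Irf7 from 6.07 ± 1.28 to 12.66 ± 1.18 CPM (log2FC +1.07, SE 0.25, adjusted p = 0.0165).

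The count in FL was 1502 of 19718 genes, 695 higher and 807 lower, and it was 904 without FL_NoUV 2, 1000 without FL_NoUV 4 and 884 without FL_UV 4. It was 953 with only the 2 groups compared, 992 with no filter and 2304 by DESeq2. Irf7 missed the threshold without FL_NoUV 2 (adjusted p = 0.0626). Further rises included Ccl7 (log2FC +3.29), Ccl2 (+3.07), Fosl1 (+3.03), Hbegf (+2.29), Tnf (+1.39), Cdkn1a (+1.08) and the clock gene Per1 (+1.82). Isg15 (+0.56, adjusted p = 0.502), Mx1 (+0.89, adjusted p = 0.242) and Cxcl10 (+0.02) were not called. Lce1j, a near-identical family member whose counts are uncertain, fell from 94.86 ± 19.01 to 5.02 ± 1.73 CPM, and Trp63, the master regulator of basal keratinocytes, fell with a log2FC of −0.60.

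In FL, 11 lists passed. Immediate early genes rose in 16 of 20 on either basis, over all genes and adjusted over the list alone (adjusted p = 1.3e-13, and adjusted p = 0.0258 with an estimated correlation). The p53 list rose in 6 of 26 and in 10 adjusted over the list alone (adjusted p = 1.6e-05, and adjusted p = 0.00699 with an estimated correlation). Interferon-stimulated genes rose in 7 of 40 and in 17 adjusted over the list alone (adjusted p = 1.9e-08, and adjusted p = 0.608 with an estimated correlation). Inflammatory genes rose in 10 of 27 and fell in 1, and adjusted over the list alone 18 rose and 1 fell (adjusted p = 1.9e-08, and adjusted p = 0.304 with an estimated correlation). Cell cycle was lower (adjusted p = 0.00206, and adjusted p = 0.701 with an estimated correlation), with 0 of 20 members called by edgeR. Epidermal differentiation fell in 3 of 25 on either basis (adjusted p = 0.000587). Markers of fibroblasts (adjusted p = 0.000484), skeletal muscle (adjusted p = 0.000722), macrophages (adjusted p = 0.00108), adipocytes (adjusted p = 0.00232) and mast cells (adjusted p = 0.0158) were higher, the muscle list by a median log2FC of +0.95. These 5 lists and epidermal differentiation each had adjusted p = 0.639 with an estimated correlation, and mast cells missed the threshold without FL_NoUV 4 (adjusted p = 0.0721). NRF2 targets (adjusted p = 0.930), heat shock genes (adjusted p = 0.299), basal keratinocyte genes (adjusted p = 0.056), circadian genes (adjusted p = 0.056) and B and plasma cell genes (adjusted p = 0.366) did not pass.

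UV in cKO skin asked for the response with K14Cre. The zinc finger gene Zfp36, which shortens the life of cytokine transcripts, rose from 100.54 ± 8.75 to 492.83 ± 125.66 CPM (n = 4 each, log2FC +2.29, SE 0.18, adjusted p = 1.3e-05). Il6 rose from 0.48 ± 0.23 to 5.62 ± 3 CPM (log2FC +3.52, SE 0.53, adjusted p = 0.00107), and Pmaip1 from 9.17 ± 3.97 to 48.03 ± 6 CPM (log2FC +2.39, SE 0.30, adjusted p = 0.000347). Sele, the endothelial receptor that slows leucocytes, rose from 2.88 ± 0.28 to 18.88 ± 4.66 CPM (log2FC +2.71). Atf3 rose from 8.48 ± 2.71 to 35.97 ± 7.38 CPM (log2FC +2.09, SE 0.26, adjusted p = 0.00029). Ifit1 reached 12.11 ± 3.59 CPM against 6.61 ± 0.23 CPM (log2FC +0.88, adjusted p = 0.0324), and Irf7 was not called (log2FC −0.09, adjusted p = 0.869).

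The count in cKO was 1917 genes, 901 higher and 1016 lower, and it was 1195 without cKO_NoUV 2, 1178 without cKO_NoUV 3 and 1276 with no filter. Ifit1 missed the threshold without any of cKO_NoUV 1 (adjusted p = 0.0524), cKO_NoUV 2 (0.0724), cKO_NoUV 3 (0.081), cKO_NoUV 4 (0.0736), cKO_UV 1 (0.0726) and cKO_UV 2 (0.117). Further rises included Ccl7 (log2FC +3.67), Cxcl1 (+3.05), Ccl2 (+2.97), Cebpd (+2.31), Tnf (+1.32) and Cdkn1a (+0.86). The mast cell protease gene Mcpt4 rose from 13.87 ± 5.19 to 41.67 ± 19.59 CPM (log2FC +1.59), but missed the threshold without cKO_NoUV 2 (0.0553), cKO_NoUV 3 (0.0526) or cKO_UV 2 (0.0539). The muscle gene Actn3 rose with a log2FC of +2.15. Lce1d fell (−2.59), as did Lce1j (−3.55), Lce1k (−3.33) and Plcxd2 (−2.07).

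In cKO, 8 lists passed. Inflammatory genes rose in 12 of 27 and fell in 1, and adjusted over the list alone 13 rose and 1 fell (adjusted p = 1.4e-06, and adjusted p = 0.459 with an estimated correlation). Immediate early genes rose in 8 of 20 and in 11 adjusted over the list alone (adjusted p = 1.4e-06, and adjusted p = 0.270 with an estimated correlation). The p53 list rose in 8 of 26 and in 9 adjusted over the list alone (adjusted p = 0.000284, and adjusted p = 0.022 with an estimated correlation). Skeletal muscle rose in 2 of 14 and in 8 adjusted over the list alone (adjusted p = 0.0001), adipocyte genes in 1 of 12 and in 6 adjusted over the list alone (adjusted p = 0.00122), and neutrophil genes in 2 of 8 and in 3 adjusted over the list alone (adjusted p = 0.0426). Each of these 3 had adjusted p = 0.761 with an estimated correlation. Mast cell genes rose in 5 of 10 and in 7 adjusted over the list alone (adjusted p = 0.00174, and adjusted p = 0.653 with an estimated correlation). Cell cycle was lower (adjusted p = 0.00156, and adjusted p = 0.836 with an estimated correlation) with 0 members called by edgeR. Interferon-stimulated genes rose in 2 of 40 and in 0 adjusted over the list alone, and the list did not pass (adjusted p = 0.0703). With a replicate block, the interferon gamma and antigen presentation list and the anagen hair follicle list passed, each with adjusted p = 0.0424. Cell cycle missed the threshold without cKO_NoUV 1 (0.0662) or cKO_UV 4 (0.129), and neutrophil genes without cKO_NoUV 1 (0.0575) or cKO_UV 2 (0.11). Anagen scores of cKO libraries ran from −0.90 to 7.65 log2 CPM.

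**Figure D2:**
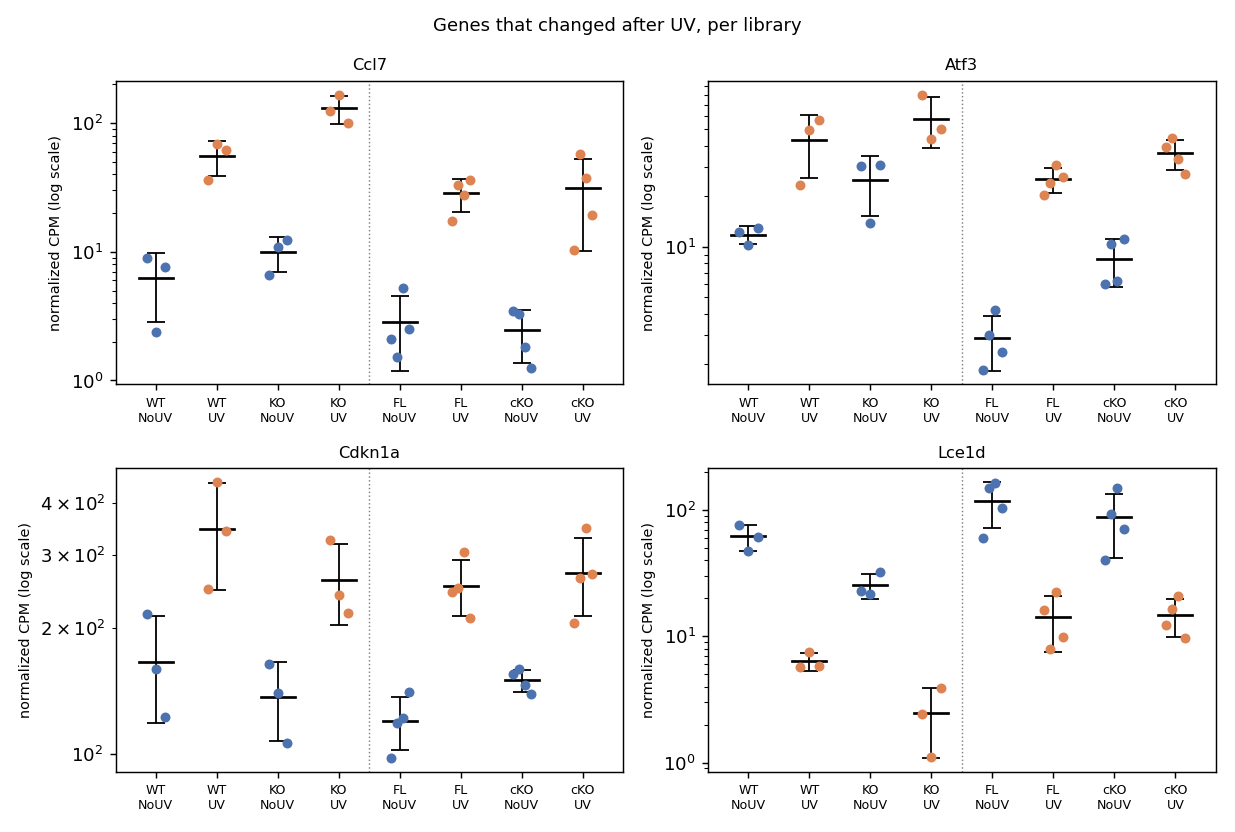
Levels of Ccl7, Atf3, Cdkn1a and Lce1d in each library as normalized counts per M on log axes (vertical) by group (horizontal). Points are libraries, bars mean ± SD, blue NoUV and orange UV; Ccl7, Atf3 and Cdkn1a had higher and Lce1d lower means after UV in all 4 genotypes.

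The difference of the UV effect between cKO and FL asked whether K14Cre-driven deletion altered the response, the question in the series title. For Irf7 the UV effect was lower in cKO by a log2 difference of −1.15 (95% interval −1.84 to −0.46, n = 4 per group, adjusted p = 0.9997), which did not pass the adjustment over all genes. The difference was −0.45 for Ifit1, +0.41 for Il6 and −1.01 for Atf3 (95% interval −1.72 to −0.30), none of them called. By edgeR, 0 genes were called, 248 had an unadjusted p under 0.05, and DESeq2 called 0. The interferon-stimulated list had a median difference of −0.48, above 0 in 4 of 40 members (adjusted p = 2.5e-08, and adjusted p = 0.964 with an estimated correlation). Immediate early genes had a median difference of −0.35 (adjusted p = 2.0e-06, and adjusted p = 0.578 with an estimated correlation) and epidermal differentiation of +0.36 (adjusted p = 5.6e-05). The interferon-stimulated score was 3.28 in both FL_UV and cKO_UV, against 2.59 in FL_NoUV and 3.02 in cKO_NoUV. The immediate early score was 6.31 in FL_UV and 6.43 in cKO_UV, against 4.88 in FL_NoUV and 5.54 in cKO_NoUV. Both differences therefore came from higher scores of cKO without UV, not from lower scores after UV. Epidermal differentiation missed the threshold without cKO_UV 3 (adjusted p = 0.171), and macrophage genes without FL_NoUV 2 (0.0867), FL_NoUV 4 (0.298), FL_UV 3 (0.125), cKO_NoUV 3 (0.269) or cKO_UV 1 (0.260). Fibroblast (adjusted p = 0.000325) and macrophage genes (adjusted p = 0.00649) were lower, and these and epidermal differentiation had adjusted p = 0.964 with an estimated correlation. No member of the 5 lists was called over all genes.

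KO against WT without UV asked what loss of VISTA does to resting skin. Wdfy1, an adaptor of Toll-like receptor signalling, was at 14.04 ± 1.06 CPM in KO and 44.49 ± 5.54 CPM in WT (n = 3 each, log2FC −1.66, SE 0.15, adjusted p = 0.00047). Vsir and Wdfy1 were the 2 genes called by edgeR, whereas 3219 had an unadjusted p under 0.05 and DESeq2 called 573. Wdfy1 was called in 18 of 19 fits and Vsir in 19 of 19. Of 85 genes tested within 5 Mb of Vsir, Vsir alone was called. Not called were the interferon-induced genes Ifit1 (15.13 ± 1.73 against 6.66 ± 2.76 CPM, log2FC +1.18, adjusted p = 0.395), Cxcl10 (13.52 ± 5.13 against 3.71 ± 1.82 CPM, log2FC +1.87, adjusted p = 0.234) and Gbp2 (102.46 against 33.53 CPM, log2FC +1.61, adjusted p = 0.161). Also not called were the differentiation keratin gene Krt1 (log2FC −1.64, adjusted p = 0.107), the cornified envelope gene Sprr1b (log2FC −2.94, adjusted p = 0.163) and the mitotic kinase gene Cdk1 (log2FC −0.96, adjusted p = 0.140). Left out in turn, libraries gave counts from 2 to 27.

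In KO without UV, 11 lists passed. Interferon-stimulated genes were above 0 in 38 of 40 members, median log2FC +0.76, with 2 called adjusted over the list alone (adjusted p = 3.1e-11, and adjusted p = 0.387 with an estimated correlation). Interferon gamma and antigen presentation was above 0 in 23 of 24, with 14 called adjusted over the list alone (adjusted p = 4.8e-10, and adjusted p = 0.313 with an estimated correlation). Cell cycle was lower by a median of −0.88, with 18 of 20 called adjusted over the list alone (adjusted p = 2.0e-11, and adjusted p = 0.313 with an estimated correlation). Epidermal differentiation was lower by a median of −0.69, with 15 of 25 called adjusted over the list alone (adjusted p = 3.0e-09, and adjusted p = 0.313 with an estimated correlation). Skeletal muscle was higher by a median of +0.68, with 10 of 14 called adjusted over the list alone (adjusted p = 3.4e-08, and adjusted p = 0.313 with an estimated correlation). T cell genes (adjusted p = 0.000277), dendritic genes (adjusted p = 0.000232) and checkpoints with VISTA partners (adjusted p = 0.000779) were higher, with 2, 4 and 0 members called adjusted over the list alone. These 3 lists each had adjusted p = 0.313 with an estimated correlation. Keratinocyte stress was lower by a median of −1.75, with 12 of 18 called adjusted over the list alone (adjusted p = 3.1e-06, and adjusted p = 0.396 with an estimated correlation). Sebaceous (adjusted p = 0.0128) and melanocyte genes (adjusted p = 0.0312) were lower, with adjusted p = 0.555 and 0.727 with an estimated correlation. Sebaceous genes missed the threshold without KO_NoUV 1 (0.0699), KO_NoUV 2 (0.0542) or WT_NoUV 2 (0.134), and melanocyte genes without KO_NoUV 2 (0.117) or WT_NoUV 3 (0.393). Over all genes, 0 members of any list were called by edgeR.

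KO against WT after UV asked the same of irradiated skin. Lyve1, a hyaluronan receptor of lymphatic vessels and resident macrophages, was at 216.79 ± 14.49 CPM in KO and 49.16 ± 11.29 CPM in WT (n = 3 each, log2FC +2.14, SE 0.29, adjusted p = 0.0241). The macrophage scavenger receptor gene Msr1 was at 34.77 ± 5.72 against 10.97 ± 2.51 CPM (log2FC +1.66, SE 0.26, adjusted p = 0.049). The nerve growth factor receptor gene Ngfr was at 13.7 ± 2.28 against 3.78 ± 0.79 CPM (log2FC +1.86, SE 0.24, adjusted p = 0.0184), and Mettl7a1 at 58.7 ± 2.95 against 33.21 ± 1.57 CPM (log2FC +0.82, SE 0.12, adjusted p = 0.0431). Across 19 fits, Ngfr was called in 16, Lyve1 in 14, Msr1 in 10 and Mettl7a1 in 8. In all, 9 genes were called, 8 higher and Vsir lower, while 3071 had an unadjusted p under 0.05 and DESeq2 called 429. The others, chosen after their values were seen, were the phosphatidylserine receptor gene Timd4 (log2FC +2.63, adjusted p = 0.0334), mt-Nd3 (log2FC +3.16), Gm20559 (log2FC +1.41) and Mmd2, whose counts were near 0. Mx1 (11.7 ± 3.21 against 4.11 ± 2.51 CPM, log2FC +1.51, adjusted p = 0.187), Irf7 (33.73 ± 8.86 against 14.31 ± 5.61 CPM, log2FC +1.24, adjusted p = 0.256) and Ifit1 (32.28 ± 14.96 against 11.73 ± 13.87 CPM, log2FC +1.46, adjusted p = 0.328) were not called. Left out in turn, libraries gave counts from 2 to 155.

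In KO after UV, 14 lists passed. Interferon-stimulated genes were above 0 in 39 of 40 members, median log2FC +1.22, with 30 called adjusted over the list alone (adjusted p = 4.2e-19, and adjusted p = 0.465 with an estimated correlation). Interferon gamma and antigen presentation had 12 of 24 called adjusted over the list alone (adjusted p = 2.9e-07, and adjusted p = 0.465 with an estimated correlation). Cell cycle was lower by a median of −0.80 with 17 of 20 called adjusted over the list alone (adjusted p = 5.7e-12), and epidermal differentiation by −0.74 with 13 of 25 (adjusted p = 2.9e-09), both with adjusted p = 0.465 with an estimated correlation. Fibroblast genes were higher by a median of +0.53, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0044, and adjusted p = 0.465 with an estimated correlation). Interferon ligands and sensors (adjusted p = 0.0274), checkpoints with VISTA partners (adjusted p = 0.0444) and Schwann cell genes (adjusted p = 0.0359) were higher. Basal keratinocyte (adjusted p = 0.0174), anagen hair follicle (adjusted p = 0.00916, median −1.41) and sebaceous genes (adjusted p = 0.00946) were lower. The last 6 lists each had adjusted p = 0.465 with an estimated correlation. Macrophage genes were higher (adjusted p = 0.0352, and adjusted p = 0.795 with an estimated correlation). Keratinocyte stress (adjusted p = 0.00343) and melanocyte genes (adjusted p = 0.0176) were lower, each with adjusted p = 0.61 with an estimated correlation. Left out in turn, libraries ended the calls of 8 of the 14 lists. Without KO_UV 2 these were sebaceous (0.111), ligands and sensors (0.111), Schwann (0.112), checkpoint, macrophage and melanocyte genes (0.398 each). Without WT_UV 1 they were checkpoint and melanocyte (0.0599 each), Schwann (0.147), ligands and sensors (0.166) and macrophage genes (0.558), and without WT_UV 3 checkpoint and Schwann (0.0756 each), anagen (0.355) and melanocyte genes (0.360). Checkpoint genes also missed the threshold without WT_NoUV 1 (0.0747) or WT_UV 2 (0.0632), basal keratinocyte genes without WT_UV 2 (0.121) or KO_UV 3 (0.0534), and melanocyte (0.115) and Schwann genes (0.139) without KO_UV 1. Over all genes, 0 members of any list were called by edgeR.

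Scores of the lists per library gave KO against WT, averaged over both treatments, an exact test over the 400 splits within treatment, whose smallest possible p is 0.005. The interferon-stimulated score averaged over treatments was higher in KO by +1.00 log2 CPM, interferon gamma and antigen presentation by +0.86 and T cell genes by +0.50, and cell cycle was lower by −0.79 (exact permutation, adjusted p = 0.029 each). Epidermal differentiation was lower in KO by −0.72 and keratinocyte stress by −1.12 (exact permutation, adjusted p = 0.0483 each). Checkpoints with VISTA partners scored 2.14 in KO_NoUV against 1.68 in WT_NoUV, and 1.68 in KO_UV against 1.37 in WT_UV. Their KO and WT libraries did not overlap in either treatment. The scores were not adjusted for skin composition. The anagen score was 0.34 in KO_NoUV against 1.1 in WT_NoUV, and −0.43 in KO_UV against 0.75 in WT_UV. The skeletal muscle score was 10.27 in KO_NoUV against 9.51 in WT_NoUV, and 10.11 in KO_UV against 9.89 in WT_UV. Genotype and tissue share were therefore not separated by these tests. In the keratinocyte experiment the lowest adjusted p of a list score between cKO and FL was 0.102 (exact permutation over 4900 splits).

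**Figure D3:**
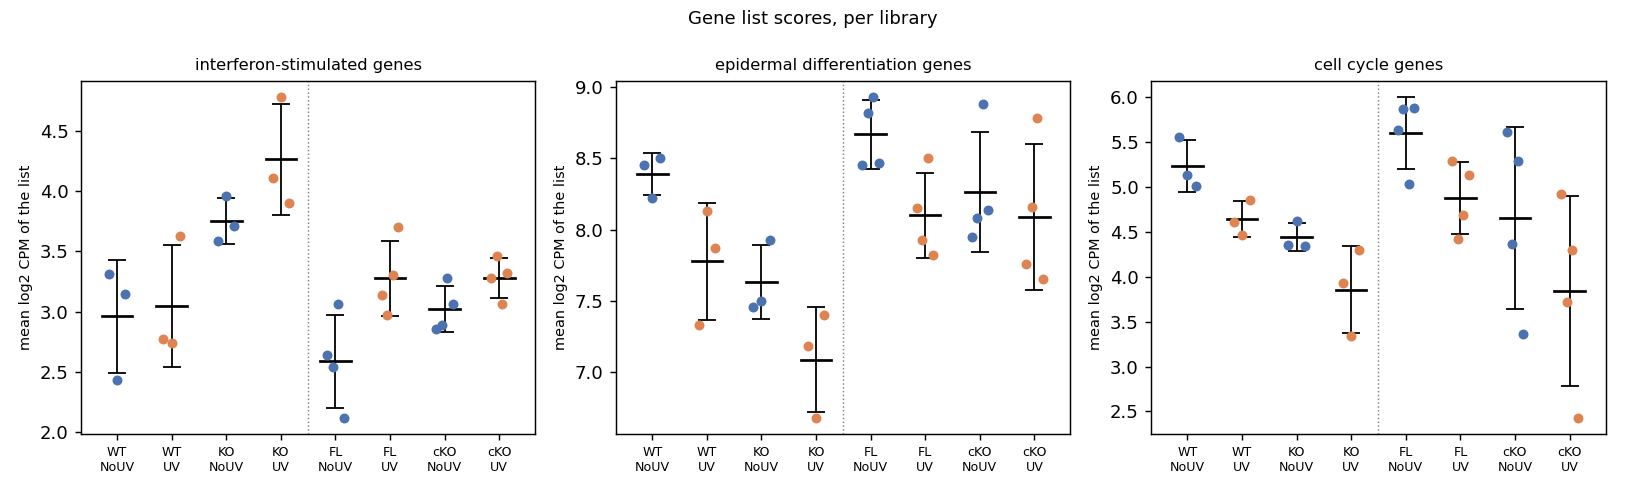
Mean log2 CPM of the interferon-stimulated, epidermal differentiation and cell cycle lists in each library (vertical axis) by group (horizontal axis). Points are libraries, bars mean ± SD, and the dotted line parts the experiments; the interferon score averaged 3.75 in KO_NoUV and 4.26 in KO_UV against 2.96 in WT_NoUV and 3.05 in WT_UV.

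cKO against FL asked what keratinocyte deletion does without and after UV. Without UV, Atf3 had the smallest p, at 8.48 ± 2.71 CPM in cKO and 2.87 ± 1.03 CPM in FL (n = 4 each, log2FC +1.53, SE 0.27, adjusted p = 0.557), and was not called. Irf7 was at 12.32 ± 4.57 against 6.07 ± 1.28 CPM (log2FC +1.03, adjusted p = 0.923), and the immediate early gene Nr4a1 at 42.15 ± 28.88 against 9.92 ± 1.26 CPM (log2FC +2.09, adjusted p = 0.665). After UV, Irf7 had a log2FC of −0.13 (adjusted p = 0.959), Ifit1 of −0.03 (adjusted p = 0.992), Isg15 of +0.92 (adjusted p = 0.865), Il6 of +0.14 and Cxcl1 of +0.21. By edgeR, 0 genes were called without UV, 928 had an unadjusted p under 0.05 and DESeq2 called 6. After UV 0 were called, 1046 had an unadjusted p under 0.05 and DESeq2 called 5. Of 83 genes tested within 5 Mb of Vsir, 0 were called by edgeR.

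Among the lists, 10 passed without UV in cKO. Interferon-stimulated genes were above 0 in 36 of 40 members, median +0.40, with 3 called adjusted over the list alone (adjusted p = 7.5e-10, and adjusted p = 0.439 with an estimated correlation). Immediate early genes were higher by a median of +0.44, with 5 of 20 called adjusted over the list alone (adjusted p = 2.9e-10, and adjusted p = 0.149 with an estimated correlation). Cell cycle was lower by −0.77 (adjusted p = 9.3e-11) and skeletal muscle higher by +0.96 (adjusted p = 8.0e-07), as were Schwann (adjusted p = 0.00187), erythroid (adjusted p = 0.00195) and circadian genes (adjusted p = 0.0033). These 5 had adjusted p = 0.439 with an estimated correlation. Keratinocyte stress (adjusted p = 2.1e-05), epidermal differentiation (adjusted p = 0.000138) and adipocyte genes (adjusted p = 0.046) passed, with adjusted p = 0.515, 0.656 and 0.835 with an estimated correlation. Epidermal differentiation missed the threshold without cKO_NoUV 1 (0.102), and adipocyte genes without FL_NoUV 2 (0.22), FL_NoUV 4 (0.0828), cKO_NoUV 3 (0.151), cKO_NoUV 4 (0.442) or cKO_UV 3 (0.0559).

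In cKO against FL after UV, 13 lists passed, each with adjusted p = 0.634 with an estimated correlation. Cell cycle was lower by −0.83 (adjusted p = 1.7e-11), fibroblast genes by −0.53 (adjusted p = 1.0e-05), macrophage genes by −0.51 (adjusted p = 0.000657) and anagen genes by −2.84 (adjusted p = 0.00191), and skeletal muscle was higher by +1.07 with 7 of 14 called adjusted over the list alone (adjusted p = 1.1e-09). Interferon gamma and antigen presentation (adjusted p = 0.0127), circadian, adipocyte and Schwann genes (adjusted p = 0.00764 each), erythroid (adjusted p = 0.0143) and endothelial genes (adjusted p = 0.0392) were higher, and melanocyte (adjusted p = 0.0119) and keratinocyte stress genes (adjusted p = 0.0392) lower. Cell cycle, fibroblast and muscle were called whichever library was left out. Without cKO_UV 4 circadian and melanocyte (0.053 each), Schwann (0.132), erythroid (0.182), endothelial and keratinocyte stress (0.214 each), adipocyte (0.322) and antigen presentation genes (0.380) missed the threshold. Without FL_UV 4 erythroid (0.0669), anagen and adipocyte (0.0702 each), circadian and melanocyte (0.135 each) and endothelial genes (0.332) did, and without FL_UV 1 keratinocyte stress (0.0671), anagen (0.0888), melanocyte and Schwann (0.108 each) and endothelial genes (0.151). Without cKO_UV 2 melanocyte (0.0785), keratinocyte stress (0.123), erythroid (0.130) and antigen presentation genes (0.133) did, without FL_UV 2 endothelial (0.0741) and antigen presentation genes (0.312), and without cKO_UV 1 macrophage (0.110) and endothelial genes (0.124). Keratinocyte stress reversed without FL_UV 3 (0.863). Interferon-stimulated genes did not pass after UV (median −0.05, adjusted p = 0.973).

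The genotype effects of the experiments were compared in the joint model of 8 groups. Vsir differed without UV (log2 difference −3.05, SE 0.43, adjusted p = 0.00373) and after UV (log2 difference −2.86, SE 0.44, adjusted p = 0.014; n = 3 and 4 per group). Without UV, Vsir was the 1 gene called, while 892 had an unadjusted p under 0.05 and DESeq2 called 6. After UV 2 were called, Vsir and the X-linked gene Nexmif (log2 difference +3.42, SE 0.57, adjusted p = 0.0277), which was chosen after its values were seen. DESeq2 called 37, and 1804 had an unadjusted p under 0.05. Vsir missed the threshold after UV without KO_UV 3 (adjusted p = 0.155) or FL_UV 2 (adjusted p = 0.0509), where 0 genes were called by edgeR, and Vsir alone was called without WT_UV 2, FL_UV 3, cKO_UV 1, cKO_UV 3 or cKO_UV 4. The UV effect differed between WT and FL at 262 genes, 180 higher and 82 lower in WT. That count was 65 without WT_UV 2, 94 without WT_NoUV 1, 102 without FL_UV 3, 141 without FL_UV 1, 162 without WT_NoUV 2 and 423 without WT_UV 3, and 6 of 33 splits of the libraries gave at least 262, the real one included. Dusp5, which switches off ERK signalling, had a log2 difference of −1.93 (SE 0.38, adjusted p = 0.0127), and the histone gene Hist1h4c of +3.51 (SE 0.56, adjusted p = 0.00348), though histone counts are shared between near-identical copies. Il1b was not called (log2 difference −1.97, adjusted p = 0.112). Batch date and control genotype also differ between the experiments.

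Shared UV responses of WT and FL were counted over 18069 genes tested in both. Of 3639 genes called in WT and 1400 called in FL, 707 were called in the same direction and 2 in opposite directions (Fisher's exact test, odds ratio 4.81, p = 4.7e-157). Higher in both were 288 against 56.2 by chance, and lower in both 419 against 86.3. At an adjusted p of 0.01 the shared count was 208. Log2 fold changes correlated across genes (r = 0.497, rho = 0.523), although genes are not independent replicates. For the genotype effects, 0 genes called by edgeR were shared without UV (2 called in KO and 0 in cKO) or after UV (8 and 0), and fold changes correlated across genes with r = 0.356 and r = 0.225.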

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

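Tests of Hox genes, of a single high library, of leucocyte share, of hair growth and of other splits within a comparison were chosen after their results were seen, and those of strain variants, depth, number series and the splits of the averaged genotype effect before. In groups of 4 libraries, 11 of 180 sets held a library far from the other 3 by a Dixon test at the 95% level, where chance gives 9. Among single genes, Vsir stood at 38.54 CPM in FL_NoUV 3 against 19.4 to 22.51 in the rest of its group. Ifnb1, which encodes interferon beta, stood at 0.04 CPM in FL_UV 1. That lies below the level of 3 counts in this library (0.135 CPM), so it is not read as an outlying level. Ifit1 stood at 3.35 CPM in FL_NoUV 4 and Cxcl1 at 0.75 CPM in FL_NoUV 2. Krt6a, a keratin gene of stressed epidermis, stood at 1147 CPM in FL_UV 3, and S100a8 at 6.92 CPM in cKO_NoUV 1. Among list scores in log2 CPM, inflammatory genes stood at 2.66 in cKO_NoUV 2 and p53 targets at 5.34 in FL_UV 3. The anagen score stood at 2.03 in cKO_UV 1, and in cKO_NoUV 1 the sebaceous score stood at 7.55 and the melanocyte score at 5.75. Between the experiments, the genotype effect differed at 1 gene without UV and at 2 after UV, and the UV effect in controls at 262.

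Of 7 posterior Hox genes, 4 rose after UV in WT and 5 in KO, 0 were called by edgeR in FL and Hoxc10 alone fell in cKO, while Hoxd10 had a log2FC of −1.07 in WT and −1.12 in KO and was not called. Their median log2FC was 1.81 in WT, 1.28 in KO, −0.14 in FL and −1.37 in cKO, and the opposite sign in cKO, where Hoxc10 fell, argues against a regulation by UV alike in both experiments. Counting error is argued against by Hoxc10, with at least 137 counts in each UV library of the whole-body experiment and at most 2 in each NoUV library. Paralogs 9 and 10 exceeded paralogs 1 to 5 by a median of at least 1.03 in that experiment, so skin taken from different body positions may underlie these genes, and the labels give no position. How many of the other genes called after UV in that experiment share this source stays open, and a biological explanation was not tested. In the keratinocyte experiment, Hoxc10 counts were 2, 2, 0 and 0 in cKO_UV and 2, 112, 94 and 115 in cKO_NoUV. They were 42, 0, 52 and 128 in FL_UV and 4, 66, 146 and 120 in FL_NoUV. Body position may therefore also be mixed with UV in cKO, cKO against FL after UV and the difference of the UV effect there.

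Interferon-stimulated genes were higher in whole-body KO after UV, by a median log2FC of 1.22. Without KO_UV 2, the highest library, the score difference was 0.96, which argues against a single high library. T cell, dendritic and macrophage scores differed by 0.37 on average after UV. This argues against a larger share of the leucocytes these lists mark as the whole cause after UV. However, Lyve1 and Msr1, macrophage genes outside these lists, were called higher in KO after UV. Both differed by more than the median of 1.22, and the macrophage list also passed. A larger share of resident macrophages therefore stays open after UV. Without UV the T cell and dendritic lists had medians of +0.55 and +0.56 against +0.76 for interferon-stimulated genes (macrophage +0.03). Leucocyte share therefore stays open there too. Of 40 members, the 37 outside the gene families of chromosomes 1 and 17 had a median of 1.23, with 36 above 0. Variants in those families alone therefore do not account for the rise. Leaving out so few members could hardly move the median, and strain variants elsewhere were not tested. Litter, housing and day of harvest stay open as the labels do not give them, the list missed its threshold with an estimated correlation, and a role of VISTA is a hypothesis these data leave untested against them.

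Libraries of the keratinocyte experiment spread along their first component, which held 46.9% of the variance. It followed the anagen score over 16 libraries (Pearson's r = −0.973, permutation p = 1e-05, the smallest possible, adjusted p = 2e-05; Spearman's rho = −0.774, permutation p = 0.00075; r = −0.936 without the 2 farthest libraries), so hair growth phase is a candidate source of most of this spread. Depth is argued against (r = −0.154, permutation p = 0.602; rho = −0.018, permutation p = 0.952; r = −0.052 without the 2 farthest libraries). The number series of the sample names took 29.7% of the component's variance and stays open. The component was computed from the most variable genes of the same libraries, which can include members of the anagen list. Its correlation with the anagen score may therefore be partly built in, and the permutation p sets hair phase against no independent measure.

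Other splits of the same libraries tested chance, drawn at random where more than 100 exist. For UV in FL and UV in cKO, 1 of 35 splits gave as many genes, the real one, with 1502 and 1917 genes against at most 2 and 2 in any other. That share is under 0.05, so chance is an unlikely source. The 3 against 3 splits number 10, too few for a share under 0.05. UV in WT gave 3817 genes against at most 649, UV in KO 4552 against 0, KO against WT 2 against 3 without UV and 9 against 0 after UV. The genotype effect averaged over treatments, an added comparison, gave 1517 genes in the whole-body experiment, as many as 1 of 40 splits, the real one, with at most 2 in any other. That share is under 0.05, so chance is an unlikely source. However, 1 other split of the keratinocyte libraries called 2014 genes in the same averaged test, so a structure of the samples besides genotype stays open. For the genotype effects compared between experiments without UV, 6 of 33 splits gave as many as the 1 gene, which was Vsir (highest other 3). Most of those others keep the KO libraries together while regrouping FL and cKO, and so still measure the loss of Vsir. The count therefore cannot decide on chance, while Vsir was called in 32 of 32 fits (log2 difference −3.35 to −2.89). After UV, 1 of 33 splits gave as many as the 2 genes (highest other 1). That margin is 1 gene, and the real count was 0 without KO_UV 3 or FL_UV 2 and 1 without WT_UV 2, FL_UV 3, cKO_UV 1, cKO_UV 3 or cKO_UV 4, so chance is not taken as excluded for the count after UV. Most of the other splits with 1 gene also keep the KO libraries together. Vsir itself was called after UV in 30 of 32 fits (log2 difference −3.08 to −2.63). For the UV effect in controls, 6 of 33 splits gave at least the 262 genes (highest other 1849), and 4 of the 5 larger counts came from splits that keep the UV libraries of WT together while regrouping FL, and so measure the UV effect in WT.

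Comparisons with 0 genes cannot exceed any split. The highest other splits called 1517 genes for the difference of the UV effect in the whole-body experiment (40 of 40 splits), where that split exchanges the genotypes within 1 treatment and so measures the averaged genotype effect. They called 66 for that difference in the keratinocyte experiment (30 of 30), 20 for cKO against FL after UV (35 of 35) and 2014 for the averaged effect of cKO (40 of 40). For cKO against FL without UV (35 of 35) the highest other split called 668 genes, with FL_NoUV 1, FL_NoUV 2, FL_NoUV 4 and cKO_NoUV 1 together, which points to a structure of the samples. Counts of lists were no larger than other splits gave. As many lists passed in 10 of 10 splits for UV in WT (3 real, highest other 13), 7 of 10 for UV in KO (6, 15), 4 of 10 for KO against WT without UV (11, 12) and 2 of 10 after UV (14, 14), where 10 splits are too few. They passed in 35 of 40 for the difference of the UV effect in that experiment (7, 18), 12 of 35 for UV in FL (11, 19), 31 of 35 for UV in cKO (8, 21), 21 of 35 and 8 of 35 for cKO against FL without (10, 20) and after UV (13, 19), and 27 of 30 for the difference in the keratinocyte experiment (5, 18), so chance is not excluded for these counts.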

How the results depend on the processing

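The fits without shallow, anagen-high or low Gm42418 libraries, the position covariate and the averaged effect were chosen after the data were seen; the rest were planned, and all were run. The position covariate was fitted in the keratinocyte experiment alone, so the UV effects of the whole-body experiment were not adjusted for body position. RLE size factors kept every count of genes and of lists within 1.5 times. Each test of a named gene in a comparison, called or not, was set against its main outcome, and 0 called genes reversed. Of 454 such tests, RLE lost 3 calls, DESeq2 gained 4 and no filter lost 49. The fits with only the groups compared lost 48 and gained 1 in 366 tests, the tissue covariates lost 72 and gained 4 in 396, and the number series block lost 2 in 161. The fits without the low Gm42418 libraries lost 66 in 188 tests, those without the anagen-high libraries lost 38 and gained 4 in 235, those without the shallow libraries lost 12 in 161, and the position covariate lost 18 and gained 1 in 161. Leaving out single libraries lost 622 and gained 12 in 7020. Where a value below changed, the cause was not tested, except that leaving out libraries leaves fewer samples and no filter tests more genes.

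DESeq2 called 573 and 429 genes for KO against WT without and after UV, 3363 averaged, 2304 for UV in FL, 6 and 5 for cKO against FL, 90 averaged, 6 and 37 for the genotype effects between experiments and 715 for UV in controls. No filter gave 185 and 162 for KO against WT, 992 for UV in FL, 1276 for UV in cKO, 1 for cKO against FL without UV, 1 averaged, 4 for the genotype effects between experiments after UV and 137 for UV in controls. Only the 2 groups compared gave 1288 for UV in WT, 7493 for UV in KO, 4 for KO against WT without UV and 953 for UV in FL. The tissue covariates gave 2542 for UV in WT, 2691 for UV in KO, 1 and 469 for KO against WT and 148 averaged, and the position covariate gave 1 for cKO averaged.

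The replicate block gave 22 and 31 genes for KO against WT, 1 for cKO against FL without UV, 1 averaged, and 5 and 10 for the genotype effects between experiments. It kept the counts of UV in KO (4409) and in cKO (2553) within 1.5 times. Of the calls the report gives for these, it changed those of Irf7, Cxcl10 and 4 lists as stated there, and no other call. Over all comparisons, 454 tests of named genes lost 12 calls and gained 1, and 290 list tests lost 3 and gained 11. In the comparisons not paired by correlation, the list lost was checkpoints with VISTA partners for KO against WT after UV (adjusted p = 0.0515). Lists gained there were anagen (0.0305), NRF2 (0.042) and adipocyte (0.0481) for KO against WT without UV, adipocyte for the difference in that experiment (0.0406), basal keratinocyte for UV in FL (0.0372), melanocyte for cKO against FL without UV (0.047), basal keratinocyte (0.0479) and heat shock (0.0465) after UV, and keratinocyte stress for the difference in the keratinocyte experiment (0.0201).

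Without WT_NoUV 3 and WT_UV 3, UV in WT gave 2157 genes, KO against WT 11 and 65, and the averaged effect 3336. Without KO_NoUV 2 and KO_UV 3, UV in KO gave 1468. With an estimated correlation, 0 lists passed for UV in WT, UV in KO, KO against WT, cKO against FL and both differences, 2 for UV in FL and 1 for UV in cKO. By fry, 2 passed for UV in KO, 1 for KO against WT without UV, 4 for UV in FL, 4 for UV in cKO and 0 elsewhere. At an adjusted p of 0.01, 208 genes were shared by WT and FL.

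Leaving out each library gave 2 to 27 genes for KO against WT without UV (13 without WT_NoUV 1, 12 without WT_NoUV 2, 9 without WT_NoUV 3, 9 without WT_UV 1, 27 without WT_UV 2, 5 without KO_UV 2) and 2 to 155 after UV (155 without WT_NoUV 1, 15 without WT_NoUV 3, 19 without WT_UV 3, 2 without WT_UV 2, 4 without KO_NoUV 1, 3 without KO_NoUV 2, 5 without KO_NoUV 3, 2 without KO_UV 2 or KO_UV 3). The averaged effect ran from 235 without KO_UV 2 to 3076 without WT_NoUV 3 (784 without WT_NoUV 1, 610 without WT_UV 2, 303 without KO_NoUV 1, 280 without KO_NoUV 2, 751 without KO_NoUV 3, 773 without KO_UV 1, 809 without KO_UV 3). UV in WT ran from 2734 to 4315, UV in KO from 2832 without KO_NoUV 2 to 5683 (2992 without KO_UV 3), UV in FL from 884 without FL_UV 4 to 1696 (904 without FL_NoUV 2, 1000 without FL_NoUV 4) and UV in cKO from 1178 without cKO_NoUV 3 to 2424 (1195 without cKO_NoUV 2). UV in controls ran from 65 without WT_UV 2 to 423 without WT_UV 3 (94 without WT_NoUV 1, 162 without WT_NoUV 2, 141 without FL_UV 1, 102 without FL_UV 3). The genotype effects between experiments ran from 1 to 2 without UV (2 without cKO_NoUV 1) and from 0 to 8 after UV (0 without KO_UV 3 or FL_UV 2; 1 without WT_UV 2, FL_UV 3, cKO_UV 1, cKO_UV 3 or cKO_UV 4; 4 without FL_NoUV 4, 6 without FL_UV 1 or cKO_UV 2, 7 without WT_UV 3, 8 without FL_NoUV 3). Both differences and cKO against FL stayed at 0 genes by edgeR.

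Counts of lists ran from 2 without WT_NoUV 3 to 5 without WT_UV 3 for UV in WT, 4 without KO_NoUV 1 to 7 for UV in KO, 10 to 13 and 8 without KO_UV 2 to 15 for KO against WT, 1 without WT_NoUV 1 to 10 for the difference in that experiment, 10 to 14 for UV in FL, 8 to 13 without cKO_UV 1 for UV in cKO, 9 to 15 without cKO_NoUV 1 and 7 without FL_UV 4 to 16 for cKO against FL, and 4 to 11 without cKO_UV 1 for the difference in the keratinocyte experiment. List directions reversed with 1 library left out in 5 cases. For the difference in the whole-body experiment these were epidermal differentiation (adjusted p 0.0303 to 0.940, and 0.048 without WT_UV 1) and cell cycle (0.00236 to 0.957, and 0.0029 without KO_UV 2). For that in the keratinocyte experiment they were anagen (0.00306 to 0.967, and 0.0499 without cKO_NoUV 1) and cell cycle (0.000895 to 0.967, and 0.0224 without cKO_UV 4), and for cKO against FL after UV keratinocyte stress (0.000322 to 0.863, the last without FL_UV 3).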

Other observations

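The averaged genotype effect was added after the values were seen, while the tests of gene length, clock genes, glucocorticoid response and Nnt were written before theirs. Over both treatments, KO differed from WT at 1517 genes, 800 higher and 717 lower, 6035 had an unadjusted p under 0.05, and leaving out each library gave 235 (without KO_UV 2) to 3076 (without WT_NoUV 3). With covariates for skeletal muscle and anagen scores the count was 148, 136 higher and 12 lower. The progesterone receptor gene Pgr (13.41 CPM in KO against 1.51 in WT, n = 6 each, log2FC +3.13, SE 0.38, adjusted p = 0.00281), the growth regulator gene Greb1 (log2FC +2.28) and the oxytocin receptor gene Oxtr (50.62 CPM against 14.63, log2FC +1.74) were higher. So were the interferon-induced GTPase genes Iigp1 (log2FC +2.33), Igtp (+1.79) and Irgm2 (+1.67), and 23 of 40 interferon-stimulated genes. Krt1 (2288 CPM in KO against 6412 in WT, log2FC −1.47), Sprr1b (−2.52), the water channel gene Aqp3 (−1.33) and the mitotic kinase gene Aurkb (−1.27) were lower. In cKO against FL the averaged test called 0 genes by edgeR, 2171 had an unadjusted p under 0.05 and DESeq2 called 90.

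Longer genes were lower after UV. Spearman's rho across genes between genomic span and log2FC was −0.322 in WT, −0.375 in KO, −0.352 in FL and −0.396 in cKO, below every other split of the libraries in KO (−0.358) and cKO (−0.351) but not in WT (−0.342) or FL (−0.359). UV-blocked transcription of long genes may contribute in cKO, with 35 splits, though other splits came close. It stays open in KO, where 10 splits are too few for a share under 0.05, and in WT and FL.

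The log2 difference between 2 sets of clock genes of opposite phase was higher after UV by 1.22 in FL and 1.24 in cKO (exact permutation p = 0.0286 each), with 5 and 6 of 10 genes of the first set higher and 2 of 6 of the second lower in each. In WT and KO the difference was 0.92 and 1.17 (exact permutation p = 0.1 each, the smallest possible and past no threshold, and another split in KO also gave 1.17), with 2 of 10 genes higher in each and 2 and 3 of 6 lower. Libraries taken at different times of day could give this, and UV acting on the clock was not tested apart from it.

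Pdk4, Trim63 and Ucp3 rose after UV in WT, and 8 glucocorticoid response genes had a median log2FC of 0.76 in WT, 0.29 in KO, 1.08 in FL and 1.04 in cKO. Of the 8, the metallothionein genes Mt1 and Mt2 rose and Sgk1 fell in WT and in KO, and 3 rose in FL and 3 in cKO. A stress hormone response may contribute in FL and cKO (exact permutation p of the scores = 0.0286 each) and stays open in WT (exact p = 0.3) and KO (exact p = 0.2). The skeletal muscle score was also higher after UV in FL (8.79 against 7.8), cKO (9.87 against 8.63) and WT (9.89 against 9.51), but not in KO (10.11 against 10.27). Muscle share was not tested apart from this response.

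Wdfy1 was called lower in KO without UV and was not called after UV. A C57BL/6 substrain difference, with Nnt as its marker, could not be decided. Nnt had a log2FC of 0.05 (SE 0.39, 95% interval −0.71 to 0.82) without UV and of 0.4 (SE 0.39, 95% interval −0.37 to 1.17) after UV.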
